A study of Mus musculus with 11 samples.

How the data were processed

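Pancreata were taken from 6 bitransgenic Pdx1-cre/Kras*A mice, labelled pancreatic tumour, and from 5 wild-type (WT) siblings, all 30 days old. In this mouse model, cre recombinase driven by the Pdx1 promoter switches on an altered Kras allele in the pancreas. Total RNA was extracted with Trizol and purified on a column, and biotinylated cRNA was made from 6 ug of it for Affymetrix mouse arrays with 45101 probe sets, 64 of them controls. Each of the 11 arrays holds 1 mouse, and the number of arrays limits the precision of every value.

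The deposited values are linear signal intensity values per probe set, made by the authors with MAS5 according to the submitters' processing notes, which give no version and no scaling target. The values showed that the 2%-trimmed means of the arrays matched within 1% inside 3 sets, here called scaling sets. The highest set (trimmed mean 500) held tumour replicate 1 and WT replicate 5. The middle set (250.0) held tumour replicates 3 to 6, and the lowest set (215.5) held tumour replicate 2 and WT replicates 1 to 4. The trimmed means therefore differed 2.32-fold, above the limit of 1.2-fold fixed before the data were examined, and by that rule the arrays were quantile-normalized. The labels give no dates or batches.

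The gene table listed 35890 probe sets. Of these, 34945 had a single symbol and 932 had several, while 9211 probe sets of the array were not listed. A mouse RefSeq table was used to look for outdated symbols, and 0 symbols were updated. No chromosome positions were used. Control probe sets and those without a single symbol were set aside, the lowest 40% of probe sets by mean log2 signal were left out, and the brightest remaining probe set stood for each gene. This left 13369 genes.

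Differences are log2(signal + 16), tumour minus WT. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, group only, two-sided), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Standard errors (SE) come from that fit, and standard deviations (SD) are within groups. Beside each gene list stand the median difference within the lowest set (1 tumour against 4 WT arrays), that within the highest set (1 against 1), and that of a fit with the scaling set as a block. For named genes these values are summarized as counts and printed for single genes only in part. The middle set held tumour arrays only and gave no difference of its own.

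The following 30 gene lists were tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists. They were acinar digestive enzymes, acinar regulators and secretory machinery, ductal epithelium, gastric-type metaplasia and PanIN, islet endocrine, fibroblast and extracellular matrix, macrophage and monocyte, granulocyte and mast cell, T and NK cell, B and plasma cell, endothelial, adipocyte, erythroid and spleen, small intestine, and schwann cell and neuron. The others were ER stress and unfolded protein response, cell cycle and proliferation, Ras-MAPK feedback and targets, EGF receptor ligands and receptors, immediate early and heat shock, interferon response, inflammatory cytokines and acute phase, Reg family and pancreatitis response, hypoxia and glycolysis, Notch, Hedgehog and Wnt, TGF-beta and epithelial-mesenchymal transition, p53 targets and senescence, cytoplasmic ribosomal proteins, and mitochondrial oxidative phosphorylation. A sex-linked list was shown per array and not tested. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, in a single direction, and does not compare them with other genes.

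The lists, tests and thresholds, the normalization rule, most alternatives and the rule for naming genes were all set before the data were examined. That rule took Kras, Pdx1, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, and up to 3 risen and 3 fallen members of each list. It gave 148 genes, from which the text takes examples. A list score is the mean log2 value of its measured genes in an array. Single values were compared with exact permutation tests over all splits of the arrays, two-sided.

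The procedure was tested on simulated data of 13369 genes with 200 changed genes and the same group sizes. It recovered 16% of changes of 1 and 72% of changes of 2 on the log2 scale, with 4 false calls among 92. The simulated genes varied independently and far fewer changed than passed in the data (6505), so these shares need not hold there. Alternatives covered the pseudocount (1 and 64), the scaling, the filter (none or 60%), the trend, array weights, the replicate number as a block, leaving out each array, other probe set choices, other tests per gene and other list tests. After the data were seen, a common scaling target, the scaling set as a block, leaving out the 2 arrays of the highest set, and 3 covariates were added. The covariates were the beta-actin 3'/5' signal ratio, the mean of Y-linked genes and the small intestine list score. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.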

Results

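Gene expression was measured on 11 arrays, with 6 tumour-bearing pancreata and 5 WT pancreata. The comparison asks how the pancreas of 30-day-old mice with the Kras allele differs from that of their WT siblings. The median probe set signal as deposited was 87.9 ± 9.73 (SD, n = 6) in the tumour arrays and 144 ± 53.2 (SD, n = 5) in the WT arrays (exact permutation p = 0.00216, the smallest that these group sizes allow).

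The first principal component held 58.6% of the variance and separated the groups, and the second held 13.2%. Correlations between arrays were 0.837 to 0.949 among tumours, 0.723 to 0.857 among WT arrays and 0.628 to 0.745 between groups. Without WT replicate 5, the WT correlations were 0.831 to 0.857.

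Several array measures moved with the group. The beta-actin 3'/5' signal ratio, a sign of RNA integrity and labelling, was 1.42 ± 0.28 (SD, n = 6) in tumours and 2.87 ± 0.57 (SD, n = 5) in WT arrays, without overlap. The Gapdh ratio was 0.864 ± 0.152 and 1.82 ± 0.518. Hybridization controls were 6.05 ± 2.23 times the trimmed mean in tumours and 35.9 ± 30.4 times in WT arrays, with WT replicate 5 at 89.2. Y-linked genes averaged 5.15 ± 0.20 on the log2 scale in tumours and 6.45 ± 0.78 in WT arrays. Xist, the RNA that silences an X chromosome in females, stood at 11.87 ± 0.96 and 9.66 ± 1.74. The small intestine list score was 10.59 ± 2.03 and 7.29 ± 1.14, with 6.77 in tumour replicate 1 and 10.25 to 12.66 in the other tumours. Of 14 such measures, these had adjusted p = 0.00505 by exact permutation, apart from Xist (0.0303) and the small intestine score (0.0236).

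**Figure D1:**
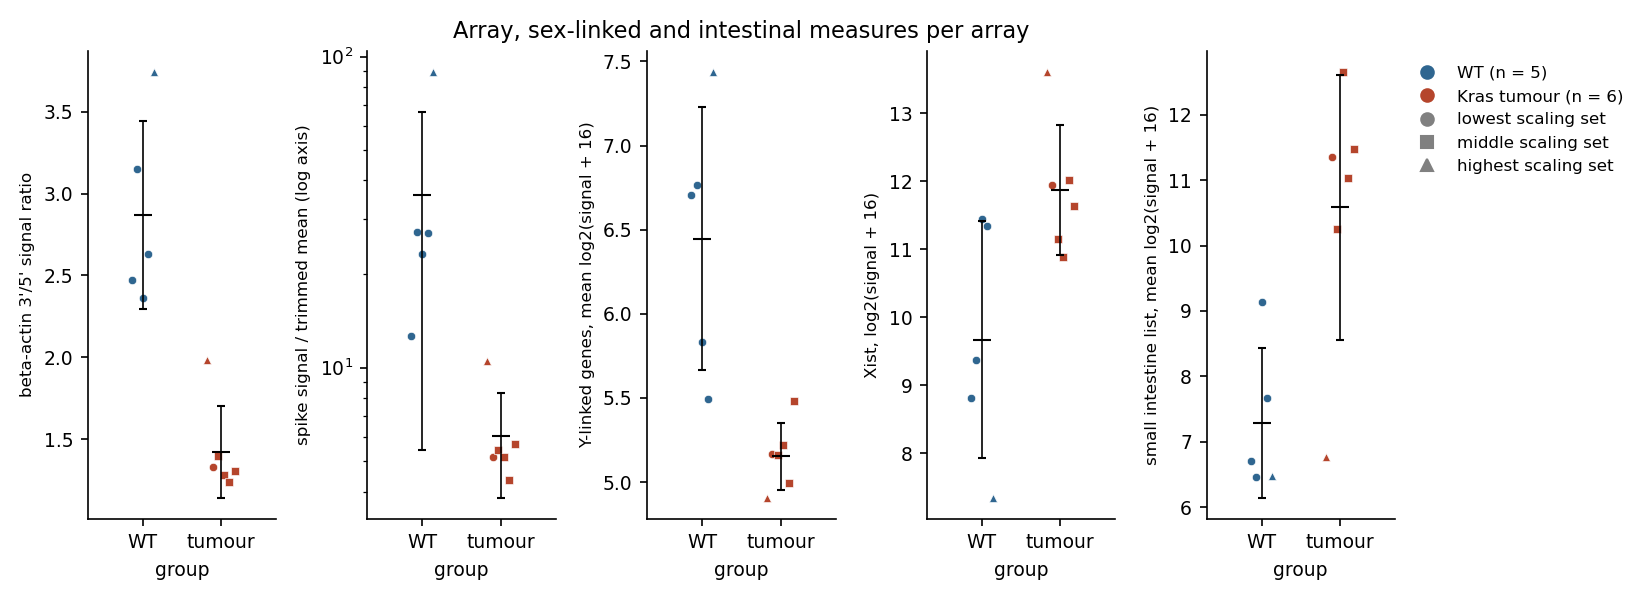
Each point is an array, shown as the beta-actin 3'/5' ratio, the hybridization control signal over the trimmed mean (log axis), and the mean log2 signal of Y-linked genes, of Xist and of the small intestine list, by group (WT n = 5, tumour n = 6). Symbols mark the scaling set and bars the mean ± SD, and the beta-actin ratio ranged from 1.24 to 1.99 in tumours and from 2.36 to 3.74 in WT arrays.

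The largest rise in the tumour group was in Chil3, a chitinase-like protein secreted by macrophages, from 5.30 ± 0.97 (SD, n = 5) to 14.68 ± 0.59 (SD, n = 6) on the log2(signal + 16) scale. Its log2 difference was 9.37, and 10.27 and 8.17 with pseudocounts of 1 and 64. Lcn2, an iron-siderophore binding protein of the acute phase response, rose by 6.82 ± 0.48 (SE) and Col1a1, a chain of type I collagen, by 6.74 ± 0.62 (SE). The peptidoglycan receptor Pglyrp1 rose by 6.38, the ductal keratin Krt7 by 6.31, the arginine-degrading enzyme Arg1 by 6.21 and the eosinophil-associated ribonuclease Ear3 by 6.18. C1qa of the complement system rose by 5.81 and the matricellular growth factor Ccn2 by 5.75. Pla2g15, a lysosomal phospholipase, rose by 5.65, the glutathione transferase Gsta4 by 5.62 and the apolipoprotein Apoc2 by 5.50.

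Among the largest falls was that of Tmed11, of the p24 family of secretory cargo receptors, from 13.64 ± 0.20 (SD, n = 5) to 5.24 ± 0.70 (SD, n = 6). Klk1b5, a kallikrein, changed by -8.25 ± 0.59 (SE), Hamp2, a hepcidin, by -8.16 ± 0.26 (SE) and the pancreatic phospholipase Pla2g1b by -8.00 ± 1.04 (SE). Tmed6 changed by -7.55, the pancreatic serpin Serpini2 by -7.39 and the pancreatic disulfide isomerase Pdia2 by -7.08. Gnmt, a methyltransferase that uses glycine, changed by -7.01, the cholecystokinin receptor Cckar by -6.90 and the endoplasmic reticulum protein Erp27 by -6.80. The amino acid transporter Slc38a5 changed by -6.73 and the zymogen granule protein Cuzd1 by -6.70. Of the 12 rises 9 had a WT mean, and of the 12 falls 6 a tumour mean, below the signal filter's limit of 6.46, so these sizes and their order depended on the pseudocount. The largest fall of these 12 was in Klk1b5 (-9.31) with a pseudocount of 1 and in Pla2g1b (-7.61) with 64, where Tmed11 stood at -9.29 and -7.19.

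All 24 of these genes had the same direction within the lowest and within the highest scaling set. Their selection for groups without overlap fixed that outcome in advance. All 24 passed with the scaling set as a block. Their smallest difference was 5.05 in size within the lowest set (Cuzd1) and 1.2 within the highest (Gsta4). With the beta-actin ratio as a covariate, Pglyrp1 no longer passed (2.60), while Col1a1 stood at 3.09, Apoc2 at 3.46, Arg1 at 9.77 and C1qa at 9.14, each past the threshold. The Col1a1 rise was 4.06 with the mean of its probe sets, and that of Pglyrp1 was 4.15 with the small intestine score as a covariate.

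Of 13369 genes tested with limma, 6505 (48.7%) passed an adjusted p of 0.05, of which 3575 were higher and 2930 lower in the tumour group. At least 2-fold changes were found in 2870 risen and 1986 fallen genes, and at least 16-fold changes in 131 and 70. The 6 tumour values lay entirely above the 5 WT values in 2210 genes and entirely below them in 1833, together 30.2% of genes, where chance gives 0.433%. With the scaling set as a block, 2579 genes were higher and 2363 lower, and 4586 genes passed in both fits in the same direction. Of the genes that passed, 99.7% kept their direction within the lowest set and 93.3% within the highest. They were called on these same arrays, and those whose groups did not overlap had to keep it. The balance between directions depended on the scaling: centring on array medians gave 5690 higher and 1309 lower genes and moved the median of all genes from 0.09 to 0.63. With the beta-actin ratio as a covariate, 4055 genes passed.

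**Figure D2:**
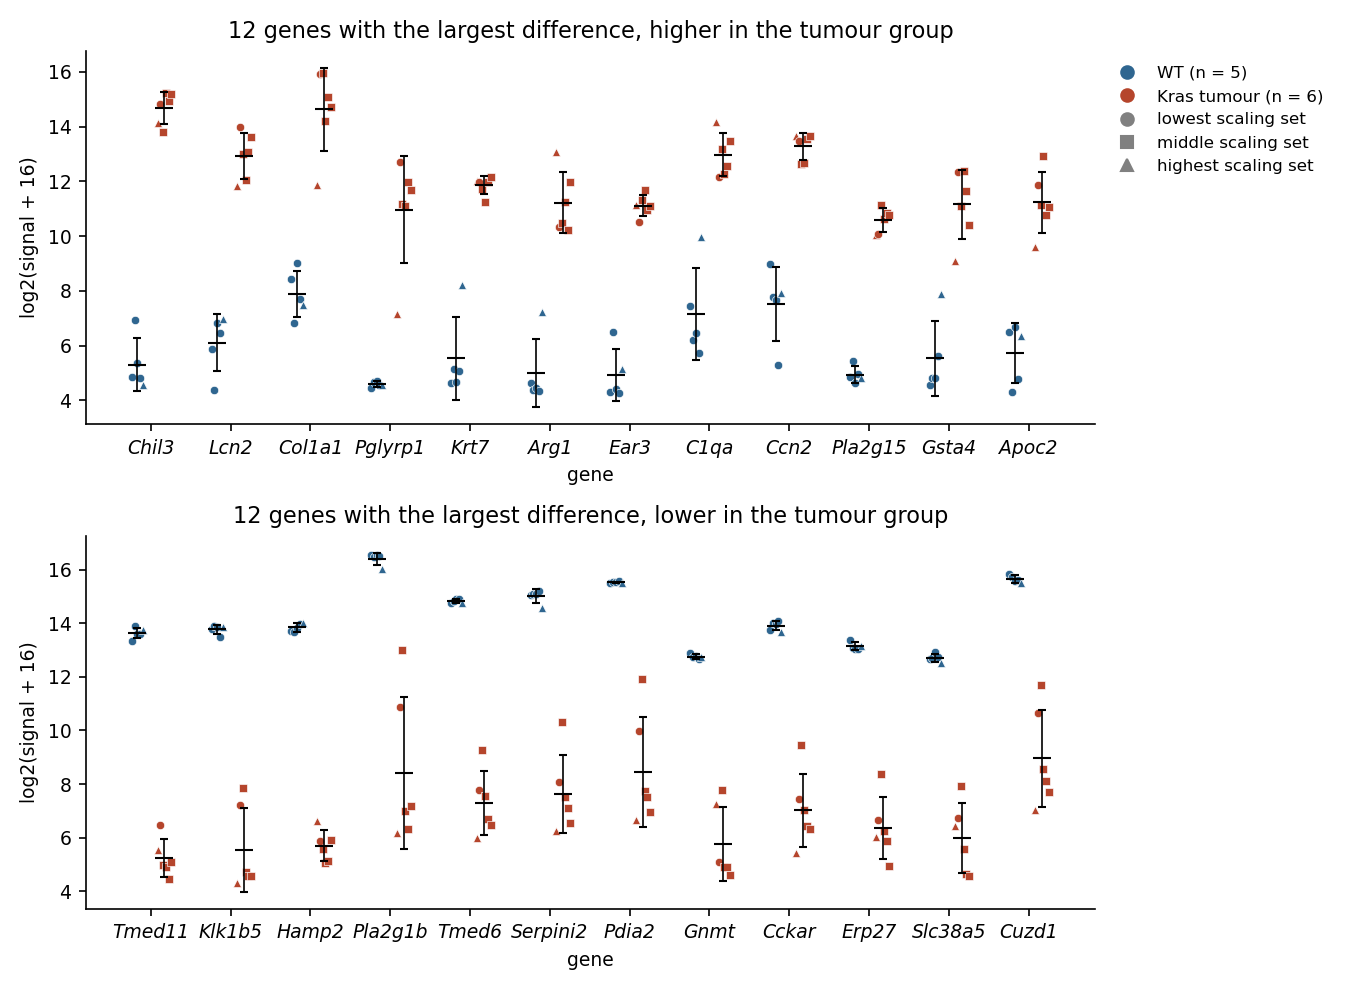
Log2(signal + 16) of the 12 genes with the largest rise (top) and the 12 with the largest fall (bottom) among genes whose groups did not overlap, per array (WT n = 5, tumour n = 6). Symbols mark the scaling set and bars the mean ± SD, and the differences run from 5.50 (Apoc2) to 9.37 (Chil3) and from -6.70 (Cuzd1) to -8.40 (Tmed11).

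Genes of the acinar cell, which makes the digestive enzymes of the pancreas, fell as a group. Of 27 measured digestive enzyme genes, 23 fell and 0 rose (24 and 0 adjusted over the list alone), with a median difference of -4.38. Pla2g1b, Serpini2 and Cuzd1 had the largest log2 differences. In WT arrays 17 of the 27 genes had a mean within 1 log2 unit of the highest normalized signal (17.16), so the sizes and the order of the falls are not settled. The list score was 11.25 ± 2.08 (SD, n = 6) in tumours and 15.57 ± 0.08 (SD, n = 5) in WT arrays. Its shift had an adjusted camera p of 4.1e-09 and an adjusted p of 0.283 with an estimated correlation. The median was -2.61 within the lowest set, -7.85 within the highest and -4.48 blocked, and -7.09 with the beta-actin ratio as a covariate.

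Among 22 acinar regulators and secretory genes, 18 fell and 1 rose (the same counts adjusted over the list alone), with a median of -4.54. Tmed6, Pdia2 and Cckar fell the most, and the transcription factor Gata6 rose by 0.86, although not past the threshold blocked (0.46). For this list camera gave an adjusted p of 4.0e-12, and 0.0679 with an estimated correlation, and the median was -4.64, -4.97 and -4.90 within the lowest set, within the highest set and blocked. Of 26 genes of the ER stress and unfolded protein response, 19 fell and 2 rose (19 and 3 adjusted over the list alone), with a median of -1.02. The asparagine synthetase gene Asns changed by -4.50 ± 0.19 (SE), the glutathione-degrading Chac1 by -4.07 ± 0.22 (SE) and Derl3, which acts in the removal of misfolded proteins, by -3.71 ± 0.25 (SE). The disulfide isomerase Pdia3 (1.45) and the stress transcription factor Ddit3 (1.35) rose, although Ddit3 did not pass with the values as deposited (1.01) or with the Y-linked covariate (1.02). The shift of the list had an adjusted p of 1.0e-06, and 0.0679 with an estimated correlation. Its median was -1.37, -0.97 and -0.999 within the lowest set, within the highest set and blocked, -0.59 with median centring and -1.58 with the Y-linked covariate.

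Genes of the ductal epithelium, which lines the channels that drain the pancreas, rose as a group, with 17 of 24 higher and 1 lower (the same counts adjusted over the list alone) and a median of 2.02. Krt7 rose the most, and the tetraspanin Tspan8 rose by 5.14 ± 0.46 (SE), or 1.79 with the mean of its probe sets. Muc1, a membrane mucin, fell by 1.97. Its shift had an adjusted p of 3.6e-05, and 0.0679 with an estimated correlation. The median was 1.96, 1.54 and 1.91 within the lowest set, within the highest set and blocked, and 0.94 with the beta-actin ratio as a covariate.

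Of 24 genes of gastric-type metaplasia and pancreatic intraepithelial neoplasia, 11 rose and 3 fell (12 and 4 adjusted over the list alone), with a median of 1.26. The rises were led by the galectin Lgals3 (5.46 ± 0.36, SE), the calcium-binding S100a6 (4.23 ± 0.23, SE) and the annexin Anxa2 (3.88 ± 0.19, SE). These 3 genes are also expressed by many other cell types. Tff2, a trefoil peptide of gastric mucus, changed by -2.93 ± 0.58 (SE). The adjusted p was 0.0113, and 0.299 with an estimated correlation, and the median was 1.38, 0.35 and 0.85 within the lowest set, within the highest set and blocked. The list did not pass with median centring (1.69), with the beta-actin ratio (0.05) or with the small intestine score (0.62) as a covariate. Its median rose to 2.61 with the lowest 60% left out and to 1.97 with the Y-linked covariate, and was 0.84 without a filter and 1.90 with the mean of probe sets. With the beta-actin covariate, 5 genes were higher and 6 lower.

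Islet endocrine genes went both ways, with 4 of 22 higher and 9 lower (the same counts adjusted over the list alone) and a median of -0.60 (adjusted p = 0.223, and 0.703 with an estimated correlation). Ppy, the gene of pancreatic polypeptide, rose by 4.72 ± 0.48 (SE), and the granin Scg2 changed by -2.05 ± 0.38 (SE). The median was -1.24 within the lowest set, 0.91 within the highest and -0.61 blocked, and ran over all settings from -0.94 with a common target to -0.13 with the small intestine score as a covariate. The Reg family and pancreatitis response genes also went both ways, with 4 of 11 higher and 4 lower (4 and 5 adjusted over the list alone). The protease inhibitor Serpina3n rose by 4.18 ± 0.51 (SE), but not past the threshold with the beta-actin ratio as a covariate (2.37). The lectins Reg3d (-5.80 ± 0.68, SE) and Reg1 (-3.53 ± 0.70, SE) and the stress protein Nupr1 (-3.38 ± 0.28, SE) fell. The median of this list was 0.47 while its mean was -0.63 and its camera direction down (adjusted p = 0.474, and 0.737 with an estimated correlation). Its median was -1.005, -1.95 and -0.81 within the lowest set, within the highest set and blocked, and -0.01 with the values as deposited. It was also below 0 with the beta-actin (-2.74, with 0 higher and 4 lower), small intestine (-1.48) and Y-linked (-0.12) covariates, a common target (-0.12), the mean of probe sets (-0.10) and the lowest 60% left out (-0.60), none past the threshold.

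All 35 measured genes of fibroblasts and the extracellular matrix rose, also when adjusted over the list alone (35 and 0), with a median of 3.51. Col1a1 rose the most, followed by the matrix glycoprotein Tnc (5.08 ± 0.55, SE) and the collagen chain Col5a2 (5.04 ± 0.49, SE). Camera gave an adjusted p of 9.7e-18, and 0.0679 with an estimated correlation, and the median was 3.69, 3.51 and 3.68 within the lowest set, within the highest set and blocked. Of 27 macrophage and monocyte genes, 25 rose and 1 fell (the same counts adjusted over the list alone), with a median of 3.57. C1qa and the signalling adaptors Tyrobp (5.23 ± 0.50, SE) and Fcer1g (5.13 ± 0.44, SE) rose the most. The lipid receptor gene Trem2 changed by -2.96 ± 0.81 (SE), with overlapping groups and WT replicate 5 at 5.11 against a mean of 9.78 in the other WT arrays. The adjusted p of the list was 2.6e-12, and 0.0679 with an estimated correlation, and its median was 3.12, 4.10 and 3.35 within the lowest set, within the highest set and blocked.

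Endothelial genes rose in 18 of 22 cases and fell in 1 (19 and 1 adjusted over the list alone), with a median of 1.37. The clotting factor carrier Vwf rose by 4.53 ± 0.41 (SE) and the tight junction gene Cldn5 by 4.12 ± 0.29 (SE), while the receptor Flt1 changed by -0.61. Flt1 did not pass blocked (-0.22), stood at 0.09 with median centring and rose past the threshold with the mean of its probe sets (0.67). For this list camera gave an adjusted p of 0.000119, and 0.106 with an estimated correlation, and the median was 1.46, 0.88 and 1.33 within the lowest set, within the highest set and blocked. Adipocyte genes had a median of -0.33, and 0.04 with median centring, with 0 of 12 higher and 4 lower (the same counts adjusted over the list alone). The adjusted p was 0.346, and 0.658 with an estimated correlation, and the median was 0.72 within the lowest set, -1.51 within the highest and -0.19 blocked, with 0 lower genes blocked. It was 0.02 without both arrays of the highest set, and -1.65 with the beta-actin and -1.22 with the small intestine covariate, none past the threshold. The lipid desaturase Scd1 had the largest fall of the list (-1.36 ± 0.37, SE) but did not pass with the values as deposited (-0.999), with median centring (-0.42), with the mean of its probe sets (-0.92), blocked (-0.58) or with the beta-actin (-2.13) or small intestine (-1.46) covariates. Schwann cell and neuron genes had a median of -0.40, -0.13 within the lowest set, -0.61 within the highest, 0.15 both blocked and with median centring, 0.16 without a filter and -1.08 with the beta-actin covariate, with 2 of 10 higher and 4 lower (the same counts adjusted over the list alone). The intermediate filament gene Gfap changed by -2.55 ± 0.51 (SE) in that list, whose adjusted p was 0.383, and 0.532 with an estimated correlation.

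Granulocyte and mast cell genes rose in 3 of 12 cases and fell in 1 (the same counts adjusted over the list alone), with a median of 0.34 (adjusted p = 0.307, and 0.545 with an estimated correlation). The calprotectin chains S100a8 (3.60 ± 0.51, SE) and S100a9 (3.55 ± 0.55, SE) rose, and the neutrophil elastase gene Elane changed by -1.99 ± 0.47 (SE). The median of this list was -0.45 with the beta-actin covariate, 0.04 with the Y-linked covariate, 0.07 with a common target, 0.18 both with the values as deposited and without a filter, 0.15 without both arrays of the highest set, 0.75 with median centring and 1.94 with the lowest 60% left out, none past the threshold. T and NK cell genes rose in 7 of 19 cases and fell in 3 (the same counts adjusted over the list alone), with a median of 0.64 and -0.43 within the highest set (adjusted p = 0.223, and 0.659 with an estimated correlation). The T cell receptor chain Cd3d (3.08 ± 0.36, SE) and the chemokine receptor Ccr7 (3.12 ± 0.42, SE) rose, although not past the threshold with the beta-actin covariate (2.19 and 1.19). The 3 fallen genes were the T cell kinase Zap70 (-2.49 ± 0.36, SE) and the coreceptors Cd8a (-1.70 ± 0.43, SE) and Cd4 (-1.52 ± 0.54, SE), which stood at -2.01, -1.98 and -2.09 blocked, each past the threshold, but with the mean of their probe sets at -0.46, -0.03 and -1.09, none past it. The T and NK cell median was -0.36 with the beta-actin covariate (0 higher and 3 lower), -0.18 with the small intestine covariate (4 and 4), 0.29 with the values as deposited, 0.24 with a common target and 1.21 with the Y-linked covariate, none past the threshold. B and plasma cell genes rose in 5 of 22 cases and fell in 1 (5 and 0 adjusted over the list alone), with a median of 0.88. Their adjusted p was 0.0514, and 0.559 with an estimated correlation. Without tumour replicate 1, their median was 1.21 with 12 genes higher (adjusted p = 0.00256), and the list also passed without tumour replicate 3 (0.89), WT replicate 1 (0.95) or WT replicate 4 (0.93), without both arrays of the highest set (10 genes higher), with array weights (1.21), with a pseudocount of 64 (0.65) and without a filter (0.88). Its direction turned with the beta-actin covariate (-1.49, with 1 higher and 5 lower) and the small intestine covariate (-0.02, with 3 and 1), neither past the threshold. The invariant chain Cd74 rose by 3.51 ± 0.36 (SE), or 1.18 and not past the threshold with the beta-actin covariate, and the B cell adaptor Blnk rose by 2.07 ± 0.24 (SE). The fallen gene, Fcrla, did not pass blocked (-1.23). Within the lowest set, within the highest set and blocked, the medians were 0.11, 1.07 and 0.34 for granulocytes, 0.56, -0.43 and 0.36 for T and NK cells, and 0.98, 0.01 and 0.64 for B and plasma cells.

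Targets and feedback regulators of the Ras-MAPK pathway rose in 16 of 22 cases and fell in 1 (the same counts adjusted over the list alone), with a median of 1.61. The early response gene Ier3 rose by 4.93 ± 0.55 (SE), and the MAP kinase phosphatases Dusp4 and Dusp6 rose by 3.77 ± 0.35 (SE) and 3.74 ± 0.29 (SE). The plasminogen activator Plau changed by -1.91 ± 0.49 (SE), although not past the threshold blocked (-1.24), and stood at 1.18 within the highest set. The test of the list gave an adjusted p of 1.6e-05, and 0.0679 with an estimated correlation, and the median was 1.37, 2.00 and 1.43 within the lowest set, within the highest set and blocked, and 0.68 with the beta-actin covariate. EGF receptor ligands and receptors rose in 6 of 10 cases and fell in 1 (7 and 1 adjusted over the list alone), with a median of 1.23 (adjusted p = 0.0514, and 0.127 with an estimated correlation). The growth factor Hbegf rose by 2.90 ± 0.31 (SE) and the receptor Erbb2 by 2.70 ± 0.28 (SE). The fallen gene was the receptor Egfr (-1.56 ± 0.32, SE, and -1.71 blocked), of whose 6 probe sets 2 were higher and 2 lower, and which did not pass with their mean (-0.0202) or with median centring (-0.64). This list passed without tumour replicate 4 (1.19), WT replicate 1 (1.37), WT replicate 4 (1.28) or WT replicate 5 (1.22), and with the values as deposited (1.23), centring on the upper quartile (1.25) and a common target (1.11), and its median was 1.15, 1.09 and 1.32 within the lowest set, within the highest set and blocked. Immediate early and heat shock genes, which can respond to tissue handling, rose in 10 of 23 cases and fell in 1 (the same counts adjusted over the list alone), with a median of 0.82 (adjusted p = 0.0655, and 0.545 with an estimated correlation). Egr2 rose by 2.93 ± 0.64 (SE), and the heat shock gene Hsp90aa1 changed by -0.88, although not past the threshold blocked (-0.77). The median was 0.45, 1.45 and 0.98 within the lowest set, within the highest set and blocked, the last past the threshold (adjusted p = 0.0439). The list also passed without WT replicate 1, whose score stood above the other WT arrays (1.35, adjusted p = 0.00286), with the values as deposited (0.88), median centring (1.45), centring on the upper quartile (0.90), a common target (0.77) and no filter (0.69). Its median was 0.47 without WT replicate 5, 0.39 without both arrays of the highest set, 0.0301 with the beta-actin covariate and 0.57 with the Y-linked covariate, none past the threshold.

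Genes of the TGF-beta pathway and epithelial-mesenchymal transition rose in 15 of 21 cases and fell in 1 (16 and 1 adjusted over the list alone), with a median of 1.33. Ccn2 rose the most, and Ltbp1, which binds latent TGF-beta, rose by 3.53 ± 0.29 (SE). The integrin Itgb6 changed by -1.10, although not past the threshold without tumour replicate 1 (-0.72). Camera gave an adjusted p of 3.6e-05, and 0.0679 with an estimated correlation, and the median was 1.69, 1.88 and 1.66 within the lowest set, within the highest set and blocked. Hedgehog and Wnt genes rose in 13 of 22 cases and fell in 0 (the same counts adjusted over the list alone), with a median of 1.19. The receptor Fzd1 rose by 3.67 ± 0.20 (SE) and the secreted Wnt antagonist Sfrp1 by 3.49 ± 0.40 (SE), or by 2.10 with the Y-linked covariate. The adjusted p was 0.00112, and 0.182 with an estimated correlation, and the median was 1.19, 1.63 and 1.17 within the lowest set, within the highest set and blocked. This list did not pass with the beta-actin covariate (0.57). Notch genes rose in 5 of 15 cases and fell in 1 (the same counts adjusted over the list alone), with a median of 0.62 (adjusted p = 0.184, and 0.283 with an estimated correlation). The Notch target Nrarp rose by 1.31 ± 0.25 (SE), or 1.43 and not past the threshold with the beta-actin covariate. Notch1 changed by -0.72, although not past the threshold blocked (-0.59), and stood at 0.70 with the mean of its probe sets. The blocked median of the list was 0.79 (adjusted p = 0.0499), and its medians within the lowest and the highest set were 0.36 and 1.10. It was 1.16 with median centring and 0.38 with the small intestine covariate.

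Inflammatory cytokine and acute phase genes rose in 18 of 28 cases and fell in 2 (19 and 2 adjusted over the list alone), with a median of 1.80. Lcn2 rose the most, followed by the endotoxin-binding protein gene Lbp (4.78 ± 0.47, SE) and the chemokine Ccl6 (4.63 ± 0.35, SE). The Lbp rise was 2.63 with the beta-actin covariate. Ccl4, a chemokine, changed by -1.43 ± 0.27 (SE), although not past the threshold with the beta-actin (-0.86) or Y-linked (-1.08) covariates, and the serum amyloid gene Saa2 by -1.08, although not past it blocked (-1.24). The adjusted p of the list was 0.000102, and 0.0535 with an estimated correlation, and its median was 1.55, 1.93 and 1.64 within the lowest set, within the highest set and blocked. Interferon response genes rose in 13 of 22 cases and fell in 1 (14 and 1 adjusted over the list alone), with a median of 1.26. The immunoproteasome subunits Psmb8 (4.53 ± 0.40, SE) and Psmb9 (3.46 ± 0.40, SE) rose the most. The antiviral gene Rsad2 changed by -1.38, although not past the threshold blocked (-1.12), and stood at 0.30 with the beta-actin covariate. The shift of the interferon list had an adjusted p of 0.00381, and 0.0838 with an estimated correlation. The median was 1.11, 1.31 and 1.29 within the lowest set, within the highest set and blocked.

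Cell cycle genes rose in 17 of 28 cases and fell in 2 (19 and 3 adjusted over the list alone), with a median of 1.31. The replication licensing factor Mcm6 rose by 3.25 ± 0.40 (SE) and the mitotic kinase Cdk1 by 2.84 ± 0.34 (SE), while the cell cycle transcription factor Foxm1 changed by -3.37 ± 0.30 (SE), or -1.73 with the mean of its probe sets. The other fallen gene, Tpx2 (-1.47), did not pass with that mean (-0.56). The test of the list gave an adjusted p of 0.000815, and 0.127 with an estimated correlation. The median was 1.11, 1.40 and 1.05 within the lowest set, within the highest set and blocked, and the list did not pass with the beta-actin covariate (0.81). Genes of p53 targets and senescence rose in 7 of 19 cases and fell in 4 (the same counts adjusted over the list alone), with a median of 0.35 (adjusted p = 0.223, and 0.545 with an estimated correlation). The cyclin-dependent kinase inhibitor Cdkn2b rose by 3.90 ± 0.43 (SE) and the growth factor binding protein Igfbp3 by 3.81 ± 0.32 (SE), and Sesn1, a sestrin, changed by -2.11 ± 0.35 (SE) and the kinase Plk2 by -1.68 ± 0.24 (SE). The median was 0.20, 1.26 and 0.52 within the lowest set, within the highest set and blocked, and 0.99 with median centring. Hypoxia and glycolysis genes rose in 12 of 22 cases and fell in 3 (13 and 3 adjusted over the list alone), with a median of 0.89. The glycolytic kinases Pfkp and Hk1 rose by 3.44 ± 0.53 (SE) and 2.75 ± 0.30 (SE). The fallen genes were Ndrg1 (-1.69 ± 0.17, SE), Bnip3 (-1.67 ± 0.23, SE) and the oxygen sensor Egln1 (-0.63 ± 0.16, SE), which stood at 0.27 with median centring. The adjusted p was 0.0192, and 0.219 with an estimated correlation, and the median was 0.76 within the lowest set and 0.41 within the highest. The list did not pass blocked (0.82, adjusted p = 0.0585) or with the beta-actin (0.49) or small intestine (0.53) covariates, and its median was 1.48 with median centring.

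Cytoplasmic ribosomal protein genes rose in 6 of 23 cases and fell in 4 (the same counts adjusted over the list alone), with a median of 0.02, a mean of 0.03 and a camera direction of down (adjusted p = 0.954, and 0.981 with an estimated correlation). Their direction depended on the scaling, since the list passed and was lower with the values as deposited (-0.94), median centring (-0.36), centring on the upper quartile (-0.92) and a common target (-1.04), with 3, 2, 11 and 15 genes lower and 0, 1, 0 and 0 higher. Rps6 changed by -1.54 ± 0.20 (SE), or -0.65 with median centring, and Rps2 by 1.36 ± 0.17 (SE), or -0.0571 with the values as deposited. Genes of mitochondrial oxidative phosphorylation rose in 6 of 34 cases and fell in 10 (the same counts adjusted over the list alone), with a mean of -0.04 (adjusted p = 0.407, and 0.815 with an estimated correlation). The median was 0.11 with the values as deposited (1 higher and 1 lower), 0.69 with median centring (15 and 0) and -0.29 blocked (1 and 10). The complex I subunit Ndufa1 changed by -1.19 ± 0.13 (SE), or -0.76 and not past the threshold with median centring, and Sdhc of complex II by 1.46 ± 0.26 (SE). The within-set medians, lowest set first, were 0.09 and 0.02 for the ribosomal list, whose blocked median was 0.07, and -0.03 and -0.56 for the mitochondrial list.

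Small intestine genes, included to show tissue next to the pancreas, rose in 10 of 14 cases and fell in 0 (the same counts adjusted over the list alone), with a median of 3.21. The apolipoproteins Apoa4 (6.37 ± 1.32, SE) and Apoa1 (6.12 ± 1.25, SE) and the fatty acid binding protein Fabp1 (5.57 ± 1.19, SE) rose the most, each with overlapping groups. For this list camera gave an adjusted p of 0.00817, and 0.532 with an estimated correlation. The median was 4.19 within the lowest set, -0.20 within the highest and 2.49 blocked. The list did not pass with the Y-linked covariate (2.24), and it had the opposite sign with the beta-actin covariate (-2.01) and with its own score as the covariate (-0.27). With the beta-actin covariate, Apoa4 stood at -2.01, Apoa1 at -2.61 and Fabp1 at -0.41. Erythroid and spleen genes rose in 0 of 7 cases and fell in 3 (the same counts adjusted over the list alone), with a median of -1.27 (adjusted p = 0.0901, and 0.182 with an estimated correlation). The anion exchanger Slc4a1 changed by -1.77 ± 0.38 (SE), although not past the threshold with the beta-actin (-0.55) or small intestine (-1.45) covariates. The erythroid list passed with the values as deposited (-1.49), median centring (-0.92), centring on the upper quartile (-1.47), a common target (-1.65) and the Y-linked covariate (-1.57), and its median was -0.60 without a filter and -0.97, -0.19 and -1.24 within the lowest set, within the highest set and blocked.

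**Figure D3:**
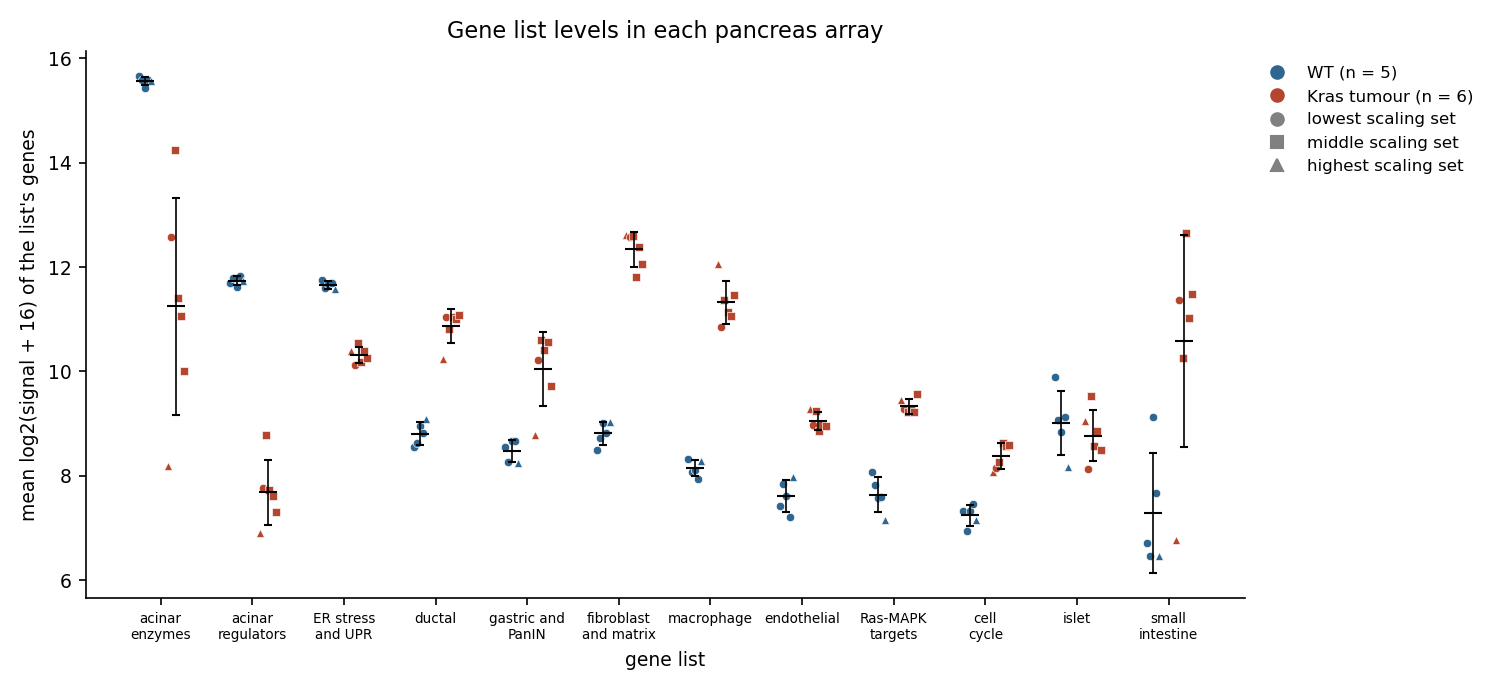
Mean log2(signal + 16) of the measured genes of 12 lists, per array (WT n = 5, tumour n = 6). Symbols mark the scaling set and bars the mean ± SD, and the small intestine score of tumour replicate 1 (6.77) lies below that of the other tumours (10.25 to 12.66).

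Of the 30 lists, 16 passed with the preset correlation, 13 higher and 3 lower. With an estimated correlation, 0 lists passed after adjustment and 11 had an unadjusted p under 0.05, while 24 passed with fry. All 16 called lists kept their direction with the scaling set as a block, and 15 kept it within both the lowest and the highest set, the exception being small intestine. Of the 147 named genes past the threshold, 145 kept their direction within the lowest set, 138 within the highest and 136 within both, and blocked 147 kept it and 123 passed. These genes too were called on the same arrays, and those whose groups did not overlap had to keep their direction within both sets. All the array measures named above, including the 3'/5' ratios, the Y-linked signal and the small intestine score, moved with the groups in which these lists changed.

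Pdx1, the pancreatic transcription factor whose promoter drives cre, stood at 8.49 ± 0.71 (SD, n = 6) in tumours and 8.43 ± 0.37 (SD, n = 5) in WT arrays, a difference of 0.06 ± 0.33 (SE). The exact permutation p was 0.857 and the limma adjusted p 0.894, and its other probe set differed by 0.15 (exact permutation p = 0.79). The Pdx1 difference was 0.73 within the lowest set and -1.17 within the highest, and -0.00188 blocked. Leaving out 1 array at a time gave -0.10 (without tumour replicate 4) to 0.28 (without tumour replicate 1), with median centring at 0.55. No listed probe set was named for Kras, and its level was not analysed here.

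The median spread of single genes within groups was smaller among tumours than among WT arrays. The spread of list scores went both ways. The acinar enzyme score had an SD of 2.08 in tumours and 0.08 in WT arrays, and the immediate early and heat shock score 0.11 and 0.63. The median over genes of the within-group SD was 0.347 in tumours (n = 6) and 0.591 in WT arrays (n = 5), a difference of -0.244 (exact permutation p = 0.026). Without WT replicate 5 the difference was -0.114 (exact permutation p = 0.248). It also did not pass with the values as deposited (-0.209), median centring (-0.0521), centring on the upper quartile (-0.113), a common target (-0.116) or the lowest 60% left out (-0.181).

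Across the 6 tumours, the acinar enzyme score was related to 6 other list scores, and no relation passed after adjustment. For the gastric and PanIN list, Pearson's r was 0.84 (exact permutation p = 0.0278, adjusted p = 0.167) and Spearman's rho 0.77 (exact permutation p = 0.103, adjusted p = 0.617), and r was 0.51 without the 2 arrays farthest from the median acinar score. For macrophages, r was -0.67 (exact permutation p = 0.147, adjusted p = 0.442) and rho -0.60 (exact permutation p = 0.242, adjusted p = 0.725), with r -0.95 without those arrays. The ductal (r 0.50, rho 0.03), matrix (0.15 and -0.03), B and plasma cell (0.49 and -0.03) and cell cycle (0.01 and 0.09) lists had adjusted exact permutation p of 0.529, 0.943, 0.529 and 0.979 for r, and 1 for each rho. Without the 2 farthest arrays their r was -0.52, 0.53, -0.36 and -0.80. The lowest and the highest scaling set held 1 tumour each. Across the 4 tumours of the middle set, r was -0.98 for the ductal list, against 0.50 over all 6, and 0.70 for gastric and PanIN, 0.67 for matrix, 0.07 for macrophages, -0.76 for B and plasma cells and -0.92 for the cell cycle, none past the threshold after adjustment (lowest adjusted exact permutation p = 0.333).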

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

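The tests of scaling, RNA integrity, sex and acinar share below, that of small intestine genes within WT arrays, and both tests on WT replicate 5, were chosen only after the results were seen.

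Values of single arrays were compared with those of their group by the gap to the nearest other array divided by the group's range. Of 370 groups of values, 60 (16.2%) exceeded the 95% limit for their size, where chance gives about 5%. Tumour replicate 1 accounted for 31 of them and WT replicate 5 for 16, the 2 arrays of the highest scaling set.

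In tumour replicate 1, the ductal (ratio 0.667), T and NK cell (0.757) and B and plasma cell (0.660) scores were lower than in the other tumours and the p53 score (0.715) was higher. Its beta-actin 3'/5' ratio (0.792) and hybridization controls (0.781) were higher, and its mean correlation with its group (0.819) was lower. Genes lower there were Pglyrp1 (0.714), Capn8 (0.803), Cd8a (0.868), Cd79b (0.674), Tspan33 (0.733), Apoa4 (0.726), Gfap (0.767) and Sox10 (0.633). Also lower were Tpx2 (0.826), Reg3g (0.645), Pkm (0.740), Tgfb1 (0.754), Itgb6 (0.757), Rps6 (0.627) and Rpl37 (0.843). Genes higher there were Vwf (0.783), Erg (0.644), Ddit3 (0.649), Adam17 (0.720), Ccl6 (0.734), Notch1 (0.730), Igfbp7 (0.639), Plk2 (0.706) and Ccng1 (0.651).

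In WT replicate 5, the B and plasma cell (0.743) and Hedgehog and Wnt (0.837) scores were lower than in the other WT arrays. Its hybridization controls (0.810) and median signal (0.925) were higher and its mean correlation with its group (0.838) was lower. Krt7 (0.856), Arg1 (0.893), S100a9 (0.766) and Notch4 (0.906) were higher there. Pla2g1b (0.884), Serpini2 (0.769), Trem2 (0.773), Gfap (0.752), Plau (0.763), Egfr (0.890) and Rpl37 (0.819) were lower.

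The immediate early score (0.726), Ppy (0.820), Scg2 (0.736) and Junb (0.888) were highest in WT replicate 1. Uchl1 (0.781) was lowest and Saa2 (0.718) highest in WT replicate 2. Tnc (0.948) and Ccr7 (0.831) were highest in WT replicate 3. Klk1b5 (0.759) was lowest and Dusp4 (0.762) highest in WT replicate 4. Ccl4 (0.630) was lowest in tumour replicate 2, Rps9 (0.759) in tumour replicate 3 and Zap70 (0.756) in tumour replicate 6.

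Probe sets without a single gene symbol were not part of the comparisons of genes and lists, and entered only where probe sets were counted singly. Of 4213 of them that passed the signal filter, 1541 passed the threshold in limma, with 608 higher and 933 lower in the tumour group.

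The acinar lists were lower and the matrix and macrophage lists higher in the tumour group. A single scaling factor per array cannot give these differences, since quantile normalization of the linear signals removes it. Whatever else goes with the scaling set is argued against as the whole cause for acinar regulators, matrix and macrophages. With the set as a block their mean differences were -4.30 (95% interval -5.26 to -3.34), 3.72 (3.16 to 4.28) and 3.14 (2.58 to 3.70). In that fit the differences come from the lowest and highest sets, which held 1 tumour array each. The 3 lists kept at least 0.875 of their median difference within the lowest set, and the enzymes 0.596. With the block the mean difference of the enzymes went from -4.31 to -4.68 (95% interval -7.78 to -1.57, so 1.57 at the nearer bound). For lower RNA integrity of the WT arrays, the beta-actin ratio did not overlap between tumours (1.24 to 1.99) and WT arrays (2.36 to 3.74). A fit with it as a covariate rests on slopes within groups, so it cannot decide whether integrity is the cause. In that fit the nearer 95% bound for regulators, matrix and macrophages stayed at 0.742 or more of the unadjusted difference. The enzymes stood at -6.77 (95% interval -11.7 to -1.87, so 1.87 at the nearer bound). For the enzymes the limit of each test was set to an interval without 0 only after stricter limits had not been met. These were 0.75 within the lowest set (0.596) and 0.5 for the nearer bound (0.433). A part of the enzyme difference from what else goes with the scaling set stays open. Lower RNA integrity stays open as a cause for all 4 lists. A difference in sex alone is argued against by WT replicates 3 and 4, whose Xist signal lay in the tumour range and whose 4 list scores lay at 0.0722 or less on a scale from 0 (other WT arrays) to 1 (tumour mean). With the Y-linked covariate the mean differences were -4.06 for enzymes (95% interval -7.84 to -0.272, with 12 of 27 genes past the threshold), -4.01 for regulators, 3.41 for matrix and 3.30 for macrophages. The Y-linked signal did not overlap between the groups either (up to 5.48 in tumours, from 5.49 in WT arrays), so this fit also rests on slopes within groups. A lower share of acinar tissue alone would raise other cell types alike, but matrix rose by 3.76 ± 0.416 (SE, log2) more than islet genes. This pair was chosen with its score differences already seen (3.52 for matrix and -0.24 for islet). The ductal and endothelial scores rose by 2.06 and 1.43. An effect of the Kras allele stays open and may account for the pattern.

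Small intestine genes differed widely between arrays within groups, from 6.77 to 12.66 among tumours. Intestinal tissue in the dissected pancreas is a candidate source, since further enterocyte, goblet and Paneth cell genes followed the score within groups (median correlation 0.761, above all of 10000 random lists, and 0.563 without tumour replicate 1). Enterocyte and goblet genes did so with (0.831 and 0.661) and without that array (0.652 and 0.448), but Paneth genes at 0.442 fell to 0.0124 without it, and 3 of 11 goblet and 3 of 8 Paneth genes are shared with other lists. Of the 14 small intestine genes, 0 are in another list. Liver tissue is argued against by hepatocyte genes (-0.115), and no sort is named in the labels. Intestinal-type expression by the tumour epithelium cannot apply to the WT arrays, which hold no tumour tissue, and stays open for the tumours. Within the WT arrays the pooled further genes also followed the score (median correlation 0.572, n = 5, and 0.443 without WT replicate 3, each above all of 10000 random lists). Enterocyte (0.597) and goblet (0.628) genes did so there, but Paneth genes did not (0.121). The random lists were matched for size and mean signal only.

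WT replicate 5 stood apart from the other WT arrays. A mislabelled tumour array is argued against by its acinar enzyme score, which lay at -9.87e-05 on a scale from 0 (other WT arrays) to 1 (tumour mean). Less labelled target on the array may contribute, since its hybridization controls were 3.56 times the median of the other WT arrays relative to the trimmed mean. That value lies between the limits of 2 and 4 set for the test, so this source stays open. No biological explanation was tested, since the labels give none for this array. The hybridization control measure also differed without overlap between tumours (4.35 to 10.5) and WT arrays (12.7 to 89.2). Less labelled target as a source of the differences between the groups was not tested.

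Among 100 splits of the 11 arrays into groups of 6 and 5, the real split included, 1 gave as many genes as the 6505 of the real groups. The highest other split gave 3635 and 95 gave 0, so chance is argued against for this count. The test cannot separate the tumour from the array measures that moved with the groups.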

How the results depend on the processing

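The settings with a common target, the scaling set as a block, covariates, or without both arrays of the highest set were chosen only after the results were seen, and the cause of the changes below was not tested unless stated. The count of 6505 genes stayed within 1.5 times in all settings but 2, from 4467 with the Y-linked covariate to 7417 without both arrays of the highest set. It was 11645 with probe sets counted singly, among 27025 tested, and 4055 with the beta-actin covariate, whose values do not overlap between the groups. Leaving out 1 array gave 5783 (tumour replicate 6) to 7204 (WT replicate 5). With the replicate number as a block 5321 passed, 5285 of them in both fits, and deviations of like-numbered arrays correlated by -0.107 to 0.0623, so the numbers were not used as pairs.

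The count of 16 lists was 16 to 19 leaving out 1 array, 20 as deposited and 11 with the beta-actin covariate. It was 0 with an estimated correlation, which allows for the correlation within lists. The spread difference of -0.244 ranged from -0.309 to -0.114 leaving out 1 array, and did not pass as deposited (-0.209), with median centring (-0.0521), upper quartile centring (-0.113), a common target (-0.116) or the lowest 60% left out (-0.181). The Pdx1 difference did not pass in any setting, from -1.14 with the beta-actin ratio as covariate to 0.55 with median centring, and from -0.10 to 0.28 leaving out 1 array.

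Some named genes reversed. Rps2 stood at -0.0571 as deposited, -0.0382 with upper quartile centring and -0.16 with a common target. Rps20 stood at -1.09, -1.08 and -1.20 there, -0.52 with median centring and -0.24 with the beta-actin covariate. With median centring, Flt1 was 0.0909, Egln1 0.27 and Notch1 0.19, and with the mean of probe sets Flt1 was 0.67 and Notch1 0.70. With the beta-actin covariate, the small intestine list was -2.01, Slc2a2 -1.89, Cd79b -2.05, Apoa4 -2.01, Apoa1 -2.61, Fabp1 -0.41, Reg3g -2.74, Atp5b -0.93, Rsad2 0.30 and Ccng1 0.0813. With the small intestine covariate, that list was -0.27, which the construction gives, Reg3g -0.69 and Atp5b -0.0807. Of the 148 named genes, 75 had no lost or reversed call in any setting in which they were measured. These 75 include Pdx1, which passed in no setting and whose sign varied. With the lowest 60% left out, only 126 of the 147 called genes were still measured. Leaving out 1 array reversed 0 of the 147 called genes and ended the call of 16, Gata6, Cldn18, Ins2, Cd4, Cd79b, Fcrla, Flt1, Plin4, Fabp4, Tspan33, Sox10, Tpx2, Reg3g, Cck, Itgb6 and Atp5b. Low signals limit the precision of fold values, which the pseudocount compresses.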

Other observations

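The lists below were chosen after the largest differences had been seen and before their own values were examined. The adjustment of their tests over the 12 lists and the members named from them were chosen after the results were seen. Their adjusted p cannot be compared with those of the lists above, which were adjusted over more lists. With an estimated correlation, the unadjusted camera p was 0.0115 for the aminoacyl-tRNA synthetases (adjusted p = 0.0344). It was lower for matrix (0.00509), TGF-beta (0.00827) and macrophages (0.00982), each with an adjusted p of 0.0679. A joint adjustment over all lists was not made.

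Genes of alternatively activated macrophages were higher in the tumour group in 13 of 18 cases and lower in 0, with a median of 2.01. Beside Chil3 and Arg1, the elastase Mmp12 (5.02 ± 0.47, SE) and the interleukin receptor Il4ra (4.36 ± 0.38, SE) rose, while Retnla stood at -0.37 and did not pass. That they differ from the other genes as a list was a hypothesis, which passed in camera (adjusted p = 0.0121 with an estimated correlation, and adjusted p = 0.0185 without Chil3 and Arg1). All 3 measured eosinophil genes rose, Ear3, the lipoxygenase Alox15 (2.98 ± 0.67, SE) and the surface lectin Siglecf (2.92 ± 0.41, SE) (adjusted p = 0.114 with an estimated correlation, and adjusted p = 0.220 without Ear3). All 15 complement genes rose, with a median of 2.67 (adjusted p = 0.0201 with an estimated correlation, and adjusted p = 0.0185 without C1qa), among them the properdin gene Cfp (5.27 ± 0.50, SE) and the inhibitor Serping1 (3.72 ± 0.20, SE). Lysosomal protease genes rose in 16 of 20 cases and fell in 0, with a median of 1.37 (adjusted p = 0.114 with an estimated correlation), led by the legumain gene Lgmn (4.75 ± 0.49, SE) and the cathepsin Ctsk (3.80 ± 0.42, SE). Of these lists, 3 macrophage, 0 eosinophil, 3 complement and 2 lysosomal genes are also in another list.

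Genes of amino acid and one-carbon metabolism fell in 21 of 26 cases and rose in 3, with a median of -1.85 (adjusted p = 0.0121 with an estimated correlation, and adjusted p = 0.0185 without Gnmt). The lysine-degrading Aass changed by -5.03 ± 0.31 (SE), the folate enzyme Aldh1l2 by -4.82 ± 0.19 (SE), the serine synthesis enzyme Phgdh by -4.32 ± 0.22 (SE) and Cbs, which makes cystathionine, by -4.25 ± 0.20 (SE). The risen genes were Mthfd1l (1.81), Got1 (1.35) and Oat (1.08), of which Oat passed blocked. Aminoacyl-tRNA synthetase genes fell in 12 of 19 cases and rose in 0, with a median of -1.06 (adjusted p = 0.0344 with an estimated correlation), led by Yars (-2.24 ± 0.21, SE) and Wars (-2.01 ± 0.26, SE). In WT arrays 23 of the 26 amino acid genes and 18 of the 19 synthetase genes lay above the median gene (8.17). Whether the falls of these 2 lists go beyond a lower share of acinar tissue was not tested. Cholesterol biosynthesis genes rose in 9 of 18 cases and fell in 2, with a median of 0.90 (adjusted p = 0.382 with an estimated correlation). Imprinted growth genes rose in 5 of 18 cases and fell in 2, with a median of 0.46 (adjusted p = 0.545 with an estimated correlation), and Igf2, a fetal growth factor, rose by 5.30 ± 0.57 (SE).

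Within the lowest set, within the highest set and blocked, the medians were 1.67, 2.10 and 2.08 for alternatively activated macrophages, 2.72, 2.58 and 2.60 for eosinophils and 2.55, 2.99 and 2.49 for complement. They were 1.15, 2.03 and 1.49 for lysosomal proteases, -1.95, -2.14 and -1.95 for amino acid metabolism and -1.28, -1.33 and -1.24 for the synthetases. For cholesterol they were 0.75, 0.28 and 0.48, and for imprinted genes 0.50, 0.18 and 0.18. The further enterocyte (16 of 30 higher, 1 lower), goblet (9 of 11 higher, 1 lower), Paneth (3 of 8 higher, 3 lower) and hepatocyte (4 of 14 higher, 4 lower) lists had medians of 2.09, 3.30, 0.03 and -0.28 (adjusted p = 0.534, 0.534, 0.984 and 0.686 with an estimated correlation). Within the lowest set, within the highest set and blocked, these were 2.43, -0.66 and 1.17 for enterocytes, 3.00, -0.54 and 1.82 for goblet cells, -1.88, -1.88 and -2.01 for Paneth cells and -0.70, 0.39 and 0.38 for hepatocytes, so the direction of none of the 4 was the same throughout.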
